A study of Mus musculus with 2 samples.

How the data were processed

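The series profiled LSD1 in differentiated primary brown adipocytes of C57BL/6 N mice and comprises 2 samples, an LSD1 immunoprecipitate made with an antibody of the submitters' own laboratory and an input DNA library without antibody, 1 library each. Per the labels' protocols, cells were kept on collagen in medium with 20% fetal bovine serum and differentiated with 850 nM insulin, 1 µM dexamethasone, 1 µM rosiglitazone, 125 nM indomethacin, 1 nM T3 and 500 µM isobutylmethylxanthine, then fixed for 5 min on day 10. Libraries were sequenced on a HiSeq 2000 and reads were mapped to mm10 with Bowtie2, per the labels' protocols, and MACS 1.41 is named in the submitters' processing notes. The Bowtie2 version, the read filters, the peak threshold and the role of the input library in peak calling were not given in the sources used here. The 1 deposited file holds, for each peak, a chromosome, start, end, name and a score, and the score is the authors' value as deposited. Its scale is not given in the sources used here, and it was used to describe, rank and select peaks within the list and, read on an assumed scale, in 1 model of chromosome X. The file gives no summits and no counts, so the depth is unknown and no interval that needs it is given.

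Peaks on chromosomes 1 to 19, X and Y were used, which is every peak of the list. Coordinates are given with the first base counted as 1. The reference was the GRCm38.p6 assembly, the same chromosomes as mm10, with the GENCODE M21 annotation, and 0 peaks reached beyond a chromosome end and 0 had the midpoint in an assembly gap. Midpoints were assigned once, in the order promoter (within 1 kb of any of 54327 protein-coding transcript starts), coding exon, untranslated region, other exon, intron and intergenic. Class shares were compared with 1000 placements of the same peak widths on the same chromosomes outside gaps, with two-sided permutation p-values by doubling and Benjamini-Hochberg adjustment over the classes. Median scores of promoter and distal peaks were compared with 100000 permutations, and again within width deciles.

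A gene was promoter-bound when a peak overlapped by at least 1 bp the region within 1 kb of any of its protein-coding starts, and had a nearby peak when a peak lay between 10 kb upstream and its end. For each of 19 gene lists the number of such members was compared with 10000 random lists of the same size from all 21853 protein-coding genes. Random lists were matched on the decile of promoter CpG content for promoters, and on gene length decile and CpG tertile for nearby peaks. CpG content of a promoter is the observed over expected CpG ratio in 1 kb around the start, the highest over the starts of a gene. The number of starts per gene was not matched. p-values were two-sided permutation values adjusted by the Benjamini-Hochberg method over the lists. All 375 entries of the lists were matched to the annotation, 1 of them through a synonym. The lists were brown fat thermogenic genes; white-fat-selective genes and repressors of the brown programme; adipogenic transcription factors; lipid storage, lipogenesis and lipolysis; fatty acid oxidation; nuclear-encoded oxidative phosphorylation; mitochondrial biogenesis, import and translation; glycolysis and glucose uptake; glucocorticoid activation and response; LSD1 and its partner proteins; cell cycle; circadian clock; cytosolic ribosomal proteins; skeletal muscle lineage; endothelial cell markers; macrophage and leukocyte markers; preadipocyte and fibroblast markers; neuronal genes; and genes of other organs. Some genes stand in more than 1 list, such as Per1, Klf9 and Nr3c1.

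Motif matching used exact consensus sequences on either strand in the 200 bp around the midpoint, against an equal number of windows outside peaks matched on GC content in steps of 2% and on CpG count. A match was found for 59035 peaks, and 140 peaks without one were left out. Fisher's exact test, two-sided, was adjusted over 24 motifs. Examples of the consensus sequences are TGASTCA for AP1, GCGCANGCGC for NRF1, CCGGAAGT for ETS, CCASYAGRKGGC for CTCF, RTTGCRYAAY for C/EBP, CAGCACCNNGGACAG for REST and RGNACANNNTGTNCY for the glucocorticoid receptor. An exact consensus is a strict criterion and misses weaker sites. GC content and the CpG ratio of centres were compared with 1 random placement per peak by 100000 permutations. Wilson 95% intervals accompany shares, Newcombe 95% intervals differences between shares, and an exact Poisson interval the ratio of peak densities.

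Genes and peaks were named by a rule set before the data were examined. It takes every peak of Kdm1a, Ucp1, Prdm16, Nrf1, Hsd11b1, Pparg, Ppargc1a and Adipoq from 10 kb upstream to the gene end, the 10 highest-scoring peaks over promoters and the 5 highest-scoring distal peaks. It further takes from each list the 3 members with the highest promoter score and the first 2 in list order without a promoter peak, with ties by coordinate. For Prdm16, Nrf1, Pparg and Ppargc1a, the lower peaks are given by score or score range. G0s2, Rfc4 and Hist1h2be are named only as neighbours or hosts of such peaks.

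Alternatives fixed before the data were examined were the upper 29591 and 5918 peaks by score, peaks merged within 500 bp, promoters of 500 bp and 2.5 kb, 1 start per gene, overlap in place of midpoints and the reverse, GC-matched placement, comparison within width deciles, unmatched gene lists, windows of 50 kb, nearby peaks without promoters, other motif windows and backgrounds, and promoter or distal peaks alone. Autosomes alone, width classes of 2% with at least 20 promoter and 20 distal peaks (10000 permutations), gene families, promoter scores per list, the intervals of motif differences and the counts of repeated or mitochondrial 32-base words were added after the data were seen. Statistics were tested on simulated data first. For random placement, 7.00% of 200 simulated random lists of 2000 peaks had p under 0.05, and 100% did with 20% of peaks planted at promoters. For list tests over 21853 genes, 4.50% of 200 simulated CpG-rich lists of 25 genes without extra binding passed when matched, against 65.0% with the unmatched Fisher's exact test, and 81.5% passed when 80% of unbound members were made bound. For score medians of 4000 simulated peaks, 4.00% of 200 unshifted sets passed, 2.50% within strata drawn at random, and 100% passed with a shift of 15%. The simulated peaks had no widths, so the comparison within width deciles was not itself tested on simulated data. For motifs in 20000 simulated windows, both planted motifs and 0 of 22 others were called.

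Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Numba 0.67.0, and figures were drawn with Matplotlib 3.10.9. The input library was not analysed here apart from its labels, since the peak list belongs to the LSD1 library, and reads were not used here. Scores depend on depth and on the caller, and wide peaks tend to score high, so scores were not compared with values from any other list.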

Results

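Genomic binding of lysine-specific demethylase 1 (LSD1, the product of Kdm1a) was mapped by chromatin immunoprecipitation and sequencing in mouse primary brown adipocytes, the heat-producing fat cells. LSD1 is a flavin-dependent enzyme that removes methyl groups from histone lysines and works in corepressor complexes with CoREST proteins and histone deacetylases. The cells came from the C57BL/6 N strain, had been passaged 2 to 3 times and were harvested on day 10 of adipogenic differentiation. The labels list 2 libraries, 1 from the LSD1 immunoprecipitate and 1 from input DNA, and the processed data are 1 list of LSD1 peaks with a score per peak. There were no replicates, so every p-value describes the peaks of this library and carries no information on the variation between cultures. The list holds no read counts, the depth is unknown, and Wilson 95% intervals given with shares cover counting error only. The score is the authors' own value for each peak and was used in this report to describe and rank peaks within the list. The question was where in the genome, and at which genes, LSD1 sits in differentiated brown adipocytes.

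The list held 59175 separate LSD1 peaks on chromosomes 1 to 19, X and Y of the mm10 assembly, covering 45.9 Mb or 1.73% of the assembled sequence. Most peaks were narrow, with a median width of 628 bp (quartiles 585 and 845) and a range from 214 to 11051 bp. Scores had a median of 111 (quartiles 86.7 and 193) and ran from 50.1 to 3224. The top of the range was tied, with 33 peaks at a score of 3100 and 1 peak above it. Such a tie may be a cap of the score, whose scale is not given in the sources used here. The 1 peak above the tie can therefore not be called the strongest. Log10 width and log10 score went together across peaks (Pearson r = 0.867), which are not independent replicates.

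Promoters were the most enriched place for LSD1. Of the 59175 peak midpoints, 13142 lay within 1 kb of a protein-coding transcript start, 22.2% (21.9 to 22.5%) against a mean of 2.66% for the same peaks placed at random on their chromosomes, an 8.34-fold excess. Coding exons held 1.88% of midpoints (1.53-fold), other exons 2.75% (1.47-fold) and untranslated regions 1.48% (1.08-fold). Introns, with 24138 midpoints, held 40.8%, slightly below the 42.3% of the random placements. Intergenic sequence held 18276 midpoints, 30.9% against 50.6% by chance (0.611-fold). Each of these differences passed the two-sided permutation test with 1000 placements (adjusted p = 0.0024, the smallest the permutations can give, and adjusted p = 0.028 for untranslated regions). When random sites were matched on GC content the promoter excess was 1.92-fold (11.6% by chance, permutation p = 0.002, the smallest the permutations can give), and it was 12.7-fold with promoters of 500 bp and 4.82-fold with promoters of 2.5 kb. The small departures of introns and untranslated regions changed direction under other promoter or overlap definitions or among higher-scoring peaks, and so did the excess of coding exons when any overlap counted (0.974-fold) and of other exons among the 5918 highest-scoring peaks (0.828-fold).

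**Figure D1:**
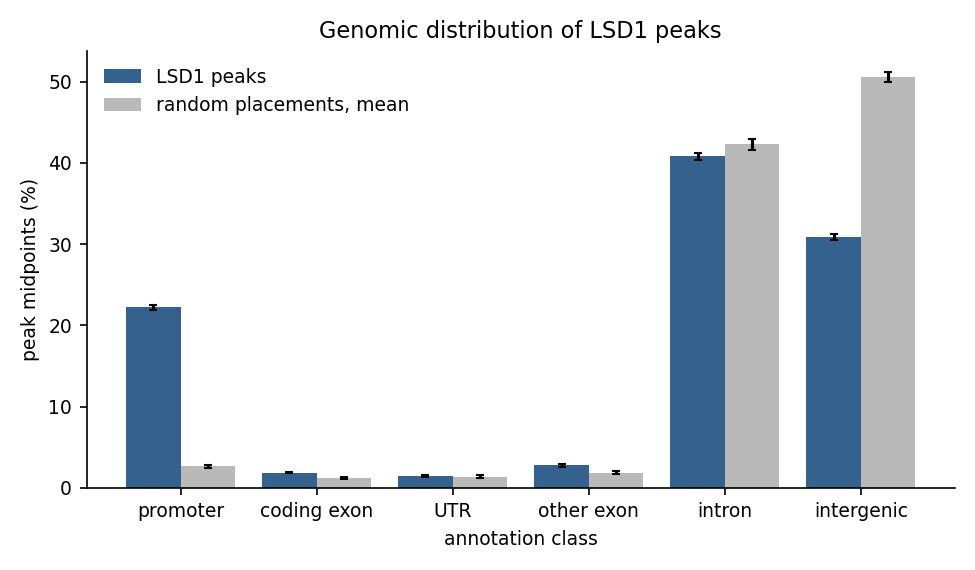
Percent of LSD1 peak midpoints (y axis) in each annotation class (x axis), with Wilson 95% intervals, beside the mean of 1000 random placements of the same peaks with their lowest and highest values. Promoters held 22.2% of peaks against 2.66% by chance, and intergenic sequence 30.9% against 50.6%.

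Away from promoters, 13808 peaks (23.3%) lay 1 to 10 kb from the nearest protein-coding start, 17057 (28.8%) lay 10 to 50 kb away and 15168 (25.6%) lay farther. The median distance over all peaks was 13193 bp. Midpoints of promoter peaks had a median 18 bp downstream of the nearest start (quartiles -129 and 223 bp), with 54.2% on the downstream side. These peaks were chosen within 1 kb on either side of a start. A median near the start and a near-even split thus follow in part from that choice, and random sites were not compared. At the gene level, 12199 of 21853 protein-coding genes (55.8%, 55.2 to 56.5%) had a peak overlapping the region within 1 kb of a start, and 15264 (69.8%) had a peak between 10 kb upstream and their end. Occupancy followed the CpG content of the promoter. Genes in the lowest decile of promoter CpG content were bound in 3.48% of cases with a median score of 99.6, and genes in the highest decile in 93.4% of cases with a median score of 438.

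Promoter peaks also had the higher scores. Their median score was 248 (quartiles 116 and 485), against 102 (quartiles 84.5 and 144) for the 46033 distal peaks, those more than 1 kb from any start. The share of peaks at promoters stayed between 9.87 and 10.7% in the 5 lowest score deciles, was 26.4% in decile 8 and 42.5% in decile 9, and reached 73.3% in decile 10. The difference in medians of 146 passed a two-sided permutation test (p = 1e-05, the smallest the permutations can give). Promoter peaks were wider as well, with a median of 933 bp against 603 bp, and within width deciles the mean difference in median score was 35.7 (permutation p = 1e-05, the smallest the permutations can give). This came from the wider peaks. The difference was between 0 and 0.880 in the 5 narrowest width deciles, of which decile 2 alone passed (0.860, unadjusted permutation p = 0.0282), and between 9.32 and 211 in the 5 widest (permutation p = 0.0001 in each, the smallest the permutations can give). The widest decile spans 1182 to 11051 bp, so width is not held there. In 68 narrower width classes, each spanning 2% and chosen after the data were seen, 57253 peaks of 492 to 2006 bp were compared. The mean difference was 70.2 (permutation p = 0.0001, the smallest possible), and the promoter median was higher in 62 classes. Wide peaks weigh more in this mean than in the mean over deciles, so 70.2 and 35.7 are not comparable. In the 23 of these classes that lie in the widest decile all promoter medians were higher. Their mean difference was 147 (permutation p = 0.0001), against 211 for the whole decile. Wider peaks than these were too few for such a comparison.

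**Figure D2:**
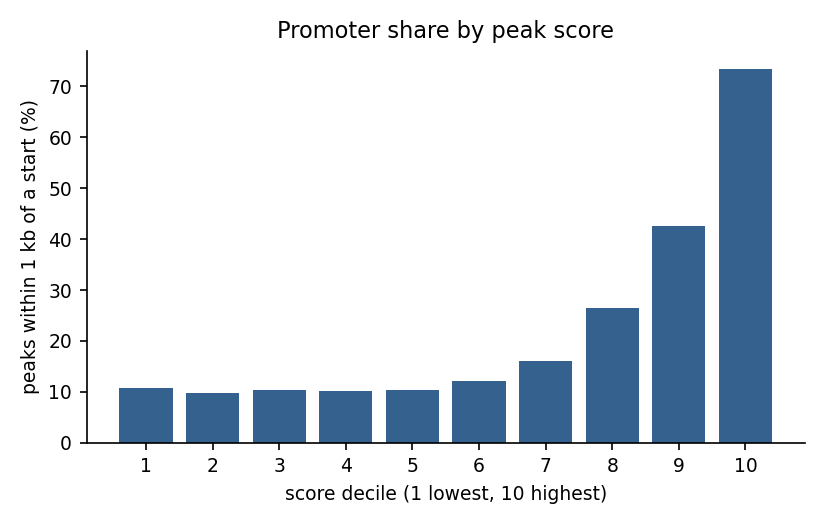
Percent of LSD1 peaks with the midpoint within 1 kb of a protein-coding transcript start (y axis) in each decile of the deposited peak score (x axis), without error bars. Between deciles 1 and 10 the share went from 10.7% to 73.3%.

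Genes chosen in advance for their place in LSD1 and brown fat biology showed different patterns of occupancy. Ucp1, which encodes the uncoupling protein that lets brown fat mitochondria release heat (chromosome 8, 83290352–83298452), had no peak from 10 kb upstream to its end. Prdm16, a transcriptional regulator of brown fat identity (chromosome 4, 154316125–154636873, minus strand), had 17 peaks with scores from 64.5 to 206. Its highest was a promoter peak at 154637269–154638252 (score 206), followed by an intronic peak at 154535851–154536877 (score 204), and a peak over its annotated start at 154636494–154637164 scored 68.1. Nrf1, encoding nuclear respiratory factor 1, a transcription factor of mitochondrial genes (chromosome 6, 30047988–30153458), had a wide promoter peak at 30047554–30049686 with a score of 763 and 3 intronic peaks with scores of 54.99, 99.98 and 79.18. Ppargc1a, the coactivator that drives mitochondrial biogenesis (chromosome 5, 51454250–51567726, minus strand), had its highest peak in an intron at 51551601–51553141 (score 403), with the midpoint 1520 bp downstream of a start. A promoter peak of Ppargc1a at 51553707–51554402 scored 95.6, and its other intronic peaks scored 85.2, 85.0 and 78.6.

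Pparg, the nuclear receptor that commands adipocyte differentiation (chromosome 6, 115360951–115490399), had a promoter peak at 115360437–115361298 with a score of 401 and 5 others, 4 of them intronic and 1 intergenic, with scores from 81.3 to 130. Hsd11b1, whose enzyme regenerates active glucocorticoid inside the cell (chromosome 1, 193221634–193264075, minus strand), had a promoter peak at 193242022–193242742 (score 89.1) and intronic peaks with scores of 174, 119 and 92.0. The fifth peak in the Hsd11b1 window, at 193272514–193273390 (score 125), lay 265 bp from the start of its neighbour G0s2, an inhibitor of lipolysis. Adipoq, encoding the adipocyte hormone adiponectin (chromosome 16, 23146536–23158028), had a promoter peak at 23147195–23147791 with a score of 76.0 and an intergenic peak at 23136670–23137256 with a score of 78.7, nearer to Rfc4. Kdm1a itself (chromosome 4, 136550540–136602723, minus strand) had 5 peaks. Of these, 2 were promoter peaks at 136601318–136601908 (score 77.6) and 136602129–136602722 (score 87.5), 2 were intronic at 136559815–136560411 (score 97.9) and 136581843–136582430 (score 89.2), and 1 covered another exon at 136584038–136584720 (score 99.2). All Kdm1a and Adipoq scores were below the median of 111 for the whole list.

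Replication-dependent histone genes, which supply chromatin with histones during DNA synthesis, were frequent among the highest scores. Of the 34 peaks at or above the tied score of 3100, 14 overlapped a histone promoter. The 10 highest-scoring peaks over promoters were taken from this tie in coordinate order, and 9 of them lay in the large histone cluster on chromosome 13, a share that depends on that order. The single top peak at 23549989–23553104 (score 3224) covered Hist1h1d and Hist1h4f. At the tied score of 3100, the peak at 21714473–21718955 covered Hist1h2ai, Hist1h2bl and Hist1h3h, 21785444–21789151 covered Hist1h2an and Hist1h2bp, and 21807191–21812610 covered Hist1h2ao, Hist1h2bq and Hist1h4m. The peak at 21830937–21835372 covered Hist1h2ap, Hist1h2br and Hist1h4n, 22034733–22038607 covered Hist1h2ah and Hist1h2bk, and 22039906–22044443 covered Hist1h2ag, Hist1h2bj and Hist1h4i. The peak at 23560552–23566984 reached Hist1h3e, and the widest peak of the list, at 23567265–23578315, reached 5 genes, Hist1h2ad, Hist1h2ae, Hist1h2bf, Hist1h2bg and Hist1h3d. Outside the cluster, the promoter of Phf12, a component of a Sin3 corepressor complex, carried a peak at the same score (chromosome 11, 77981242–77983248). Histone genes share sequence, and a median of 17.4% of the 32-base words in the peaks over histone promoters occurred more than once in the genome.

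The 5 highest-scoring distal peaks, all at the tied score of 3100, lay in varied sequence. On chromosome 19, 44394105–44397990 covered the untranslated end of Scd1, the desaturase that makes monounsaturated fatty acids, 11661 bp from the nearest start. On chromosome 13, 23584321–23587559 lay at an annotated coding exon of Hist1h2be, 4342 bp from the start of Hist1h4d. On chromosome 17, 23699014–23700939 was intergenic, at -15951 bp (upstream) from the start of Cldn9, and 39842840–39849375 covered 4 annotated genes, 1 of them for ribosomal RNA, at -104412 bp from the start of Esp38. On chromosome 1, 24611022–24616636 covered 7 pseudogenes, at -26357 bp from the start of Col19a1. Of the 32-base words of that last peak, 81.7% also occurred in the mitochondrial genome. Whether misplaced reads contribute to this peak or to the one over ribosomal RNA was not tested. The distal peaks and those over the promoters above were ranked by score with ties ordered by coordinate, and no test was made of single peaks.

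Genes of lipid storage, lipogenesis and lipolysis stood out among the 19 gene lists fixed before the data were examined. Of the 27 members, 24 had a promoter peak, against 14.1 for random lists of protein-coding genes matched on promoter CpG content. The number of starts per gene, any of which can carry the peak, was not matched for any list. The highest promoter scores were at Acly, which makes cytosolic acetyl-CoA (1331, chromosome 11, 100526617–100529093), Pnpla2, the triglyceride lipase ATGL (1293, chromosome 7, 141454631–141456333), and Cfd, the adipokine adipsin (829, chromosome 10, 79891356–79893013). The lipid droplet gene Cidec and the fatty acid transporter Cd36 had none. Preadipocyte and fibroblast markers were the other list above chance, with 15 of 19 promoters occupied against 8.65. Examples were Vim, encoding the intermediate filament vimentin (699), Wnt5a, a Wnt ligand (383), and Pdgfra, a growth factor receptor of adipocyte precursors (323), while Dlk1, an inhibitor of adipogenesis, and Lum, a matrix proteoglycan, had none. These lists passed the two-sided permutation test with 10000 random lists (adjusted p = 0.0038, the smallest the permutations can give, for lipid genes and adjusted p = 0.0057 for preadipocyte markers). Among the 5918 highest-scoring peaks neither passed (adjusted permutation p = 0.418 and 0.524), and the preadipocyte markers then lay below chance by -11.2 points. The preadipocyte call also ended with promoters of 500 bp (adjusted permutation p = 0.0608), with midpoints required inside the promoter (adjusted permutation p = 0.173) and against all other genes (Fisher's exact test, adjusted p = 0.0783).

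Lists of brown and white fat genes were not distinguished from CpG-matched genes. Thermogenic genes had 19 of 26 promoters occupied against 16.1 by chance (adjusted permutation p = 0.364). Ebf3, an Ebf-family transcription factor (912), Ppargc1b, a coactivator of mitochondrial genes (834), and Zfp516, a zinc finger activator of the brown programme (767), had the highest scores. Ucp1 and Dio2, the deiodinase that activates thyroid hormone, had no promoter peak. White-fat-selective genes and repressors of the brown programme had 12 of 19 against 10.4 (adjusted permutation p = 0.770), led by Rb1, the retinoblastoma tumour suppressor (1423), Zfp423, which holds white adipocytes in their state (1272), and Tle3, a corepressor of thermogenic genes (616). The leptin gene Lep and the homeobox gene Hoxc8 had none. All 24 adipogenic transcription factors were occupied, against 20.4 by chance (adjusted permutation p = 0.136), and Egr2 (1815), Cebpa (1619) and Klf5 (1508), all activators of early or late adipogenesis, had the highest scores. No larger excess was possible for the adipogenic list, whose unadjusted permutation p was 0.026. With the 5918 highest-scoring peaks alone this list passed the test (adjusted permutation p = 0.0342).

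Metabolic and mitochondrial promoters were occupied widely, at rates that the test did not separate from other CpG-rich genes. For mitochondrial biogenesis, import and translation the expected 86.8% left little room for an excess. The adipogenic list of the same size, fully occupied against a lower 85.1%, did not pass. Fatty acid oxidation genes had 21 of 24 occupied against 17.7 (adjusted permutation p = 0.359), with Etfdh, an electron carrier to ubiquinone (1739), Acadm, the medium-chain dehydrogenase (1245), and Cpt1a, the mitochondrial gate for fatty acids (1235), highest and Cpt1b and Eci2 without a peak. Nuclear-encoded oxidative phosphorylation genes had 29 of 34 against 28.1 (adjusted permutation p = 1). Atp5d (1050.2) and Atp5b (656), subunits of ATP synthase, and Sdhb (812), a subunit of succinate dehydrogenase, scored highest, and the complex I genes Ndufs4 and Ndufa9 had none. Genes of mitochondrial biogenesis, import and translation had 22 of 24 against 20.8 (adjusted permutation p = 0.984), led by Polrmt, the mitochondrial RNA polymerase (1393), Nrf1 (763) and Tfb1m, an rRNA methyltransferase (722), with Tfb2m and Opa1 without a promoter peak. Glycolysis and glucose uptake genes had 20 of 21 against 16.3 (adjusted permutation p = 0.183). Pkm, pyruvate kinase (1603), Hk1, a hexokinase (1168), and Pdk1, an inhibitor of pyruvate dehydrogenase (1053), ranked first, and the lactate dehydrogenase gene Ldhb alone had no promoter peak.

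Regulatory and housekeeping lists were not separated from matched genes either. In the glucocorticoid, clock and ribosomal lists every member was occupied, and the unadjusted permutation p was still 0.0578, 0.104 and 0.208. No larger excess was possible, so the test could not have placed these lists above chance. All 13 genes of glucocorticoid activation and response were occupied, against 10.6 by chance (adjusted permutation p = 0.183), and the kinase gene Sgk1 (1772), the phosphatase gene Dusp1 (1275) and the receptor cochaperone gene Fkbp5 (1161) scored highest. LSD1 and its partner proteins had 23 of 25 against 21.5 (adjusted permutation p = 0.770), with Mbd3, a subunit of the NuRD complex (1988), Phf21a, which reads unmethylated histone H3 in the CoREST complex (1875), and Gse1 (1767) ahead. Zmym3, on chromosome X, and Gfi1b, a blood transcription factor that recruits LSD1, had none. All 14 circadian clock genes were occupied against 11.6 (adjusted permutation p = 0.282), led by Nfil3 (1037), Nr1d2 (977) and Arntl (872), transcription factors of the clock. All 20 cytosolic ribosomal protein genes were occupied against 17.8 (adjusted permutation p = 0.364), led by Rpl3 (916), Rpl10a (819) and Rps18 (631). Cell cycle genes had 13 of 15 against 12.6 (adjusted permutation p = 1). Aurka, a mitotic kinase (616), E2f1, which controls entry into S phase (576), and Pcna, the replication clamp (515), scored highest, while the mitotic genes Ccnb1 and Bub1 had none.

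Genes of other cell types and organs showed no difference from matched genes that passed the test. With only 1.80 macrophage and leukocyte markers and 3.36 genes of other organs expected, the test could hardly have called a deficit in these lists. Skeletal muscle lineage genes had 3 of 18 promoters occupied against 7.03 (adjusted permutation p = 0.136), which were Pax3, a factor of muscle precursors (600.1), Actn3, a sarcomere protein (572), and Mef2c (301), while the master regulators Myod1 and Myf5 had none. Endothelial markers had 4 of 12 against 4.85 (adjusted permutation p = 1), with the receptors Flt1 (481) and Tek (193) and the adhesion protein Pecam1 (178) highest and Cdh5 and Kdr without a peak. Macrophage and leukocyte markers had 2 of 12 against 1.80 (adjusted permutation p = 1), namely Cd14 (321) and Cd68 (93.6), and the pan-leukocyte gene Ptprc and the macrophage gene Adgre1 had none. Neuronal genes had 9 of 13 against 9.10 (adjusted permutation p = 1), led by Celsr3, a cadherin (1263), Tubb3, a neuronal tubulin (769), and Map2, a microtubule protein (711), with Stmn2 and, on chromosome X, Syp without a promoter peak. Genes of other organs had 1 of 15 against 3.36 (adjusted permutation p = 0.359), the cone opsin gene Opn1sw (126), and the liver genes Alb and Ttr had none. When lists were set against all other genes without matching on CpG content, 11 lists lay above and 3 below (Fisher's exact test with adjustment).

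**Figure D3:**
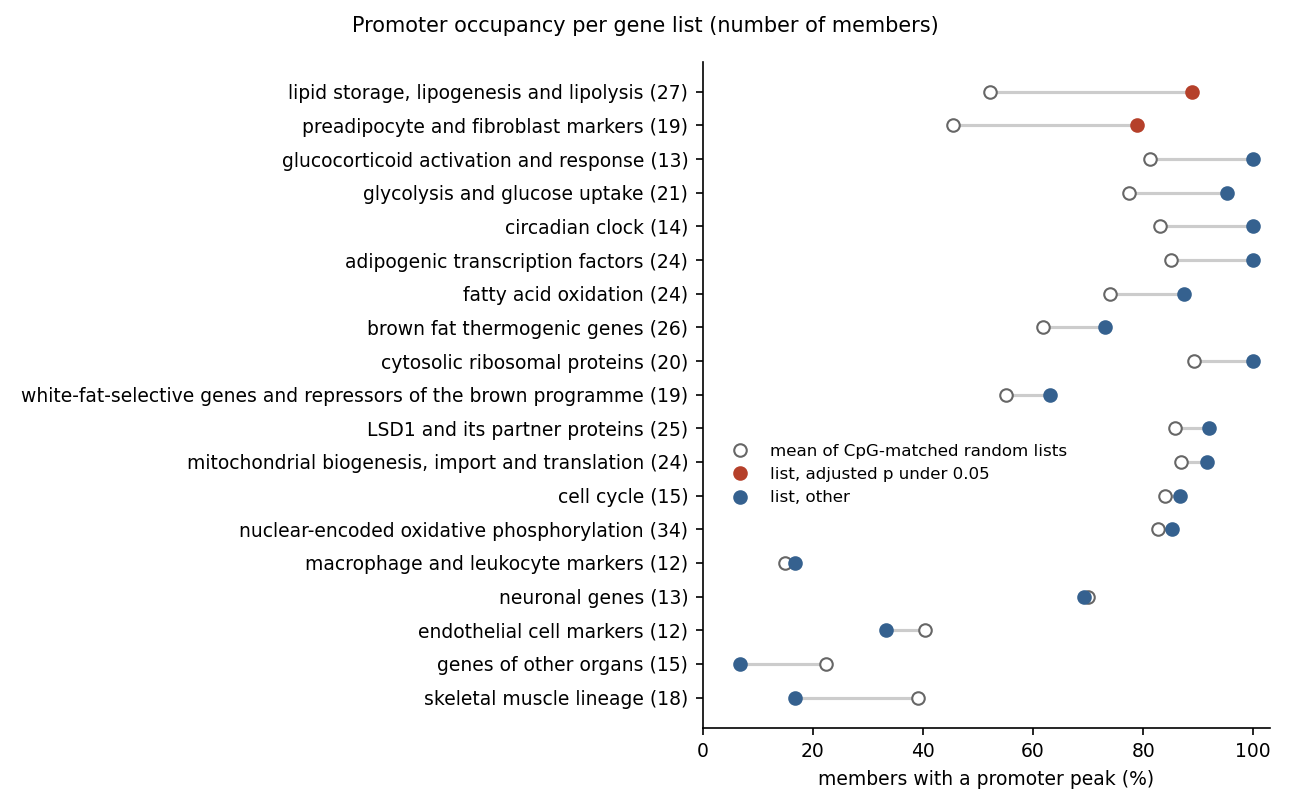
Percent of members with a peak within 1 kb of a transcript start (x axis, filled circles) in each gene list (y axis, number of members in parentheses) and the mean of 10000 random lists matched on promoter CpG content (open circles), without error bars. Lists with an adjusted permutation p under 0.05 are in red, and lipid genes stood at 88.9% against 52.2%.

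Extending the search from 10 kb upstream to the gene end, against random lists matched on gene length and promoter CpG content, again placed the lipid genes above chance, with 26 of 27 members against 18.4 (adjusted permutation p = 0.0038, the smallest the permutations can give). Macrophage and leukocyte markers were the other list above chance, with 10 of 12 against 4.78 (adjusted permutation p = 0.0304). Thermogenic genes had 20 of 26 against 19.7 (adjusted permutation p = 1), and the remaining 16 lists did not pass either, with preadipocyte markers at 16 of 19 against 12.5 (adjusted permutation p = 0.305). When peaks at promoters were left out of this search, 4 lists passed. These were lipid genes (22 of 27 against 12.7, adjusted permutation p = 0.0038, the smallest the permutations can give), adipogenic transcription factors (22 of 24 against 14.6, adjusted permutation p = 0.0114), macrophage markers (9 of 12 against 4.04, adjusted permutation p = 0.0203) and preadipocyte markers (14 of 19 against 7.97, adjusted permutation p = 0.0314). Thermogenic genes had 15 of 26 against 13.7 (adjusted permutation p = 0.781). With a window of 50 kb on either side no list passed (lipid and macrophage lists, adjusted permutation p = 0.0722), and with autosomes alone the macrophage list did not (adjusted permutation p = 0.0608). The macrophage call also ended among the 29591 highest-scoring peaks (adjusted permutation p = 0.554) and against all other genes (Fisher's exact test, adjusted p = 0.559), and the lipid call among the 5918 highest-scoring peaks (adjusted permutation p = 0.546).

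Sequence at peak centres was rich in the binding motif of AP1, the Fos and Jun dimer. An exact match to it stood in 6.55% of the 200 bp centres of 59035 peaks, against 2.77% of windows outside peaks matched on GC content and CpG count (2.36-fold, Fisher's exact test, two-sided, adjusted p = 4.81e-212). The largest fold belonged to REST, the repressor of neuronal genes, which recruits LSD1 through CoREST, with 100 centres against 4 windows (25-fold, Fisher's exact test, adjusted p = 2.18e-24). The motif of the insulator protein CTCF stood at 0.640% against 0.122% (5.25-fold, Fisher's exact test, adjusted p = 2.96e-50), and C/EBP, the adipogenic leucine zipper factors, at 0.330% against 0.108% (3.05-fold, Fisher's exact test, adjusted p = 3.99e-16). NRF1, the regulator of mitochondrial genes, stood in 1.14% of centres against 0.466% (2.45-fold, Fisher's exact test, adjusted p = 1.01e-38), and ETS factors in 0.833% against 0.391% (2.13-fold, Fisher's exact test, adjusted p = 4.20e-22). TEAD, the partners of YAP, were at 4.19% against 2.84% and RUNX at 2.46% against 1.68% (Fisher's exact test, adjusted p = 1.35e-35 and 1.97e-20). The palindrome read by the glucocorticoid receptor was at 0.183% against 0.102% (1.80-fold, Fisher's exact test, adjusted p = 0.000392), and EBF factors at 0.711% against 0.539% (1.32-fold, Fisher's exact test, adjusted p = 0.0003). The C/EBP call ended against dinucleotide-shuffled centres (1.11-fold, Fisher's exact test, adjusted p = 0.364), among the 5918 highest-scoring peaks (1.67-fold, adjusted p = 0.519) and at promoter peaks alone (1.08-fold, adjusted p = 1). The glucocorticoid receptor call ended against windows beside the peaks (1.22-fold, Fisher's exact test, adjusted p = 0.115), in 100 bp windows (1.09-fold, adjusted p = 0.845), among the 5918 peaks (adjusted p = 0.265) and at promoter peaks alone (adjusted p = 1). The EBF call ended in 100 bp windows (Fisher's exact test, adjusted p = 0.0532), among the 5918 peaks (adjusted p = 0.647) and at promoter peaks alone (adjusted p = 0.0790). The fold of REST ran from 7.89 at distal peaks to 44.9 against windows beside the peaks, and against shuffled sequence, where 100 centres stood against 0, no fold can be given. The fold of CTCF was 1.84 at promoter peaks alone.

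Of the 24 motifs, 19 were more frequent at peak centres, and the others among them were KLF/SP, CREB/ATF, YY1, the NF1 palindrome, GFI1, STAT, USF, ZBTB33 and ZNF143, with folds from 1.22 for GFI1 to 8.50 for ZNF143. AP1, TEAD, STAT, CTCF and REST passed in every alternative run, and each of the other 14 lost its call in at least 1 of them. The CCAAT motif of NFY was the 1 motif less frequent, at 4.55% against 5.24% (0.870-fold, Fisher's exact test, adjusted p = 1.16e-07), and this turned to an excess of 1.10 points against windows 1 kb to either side of the peaks. The test did not separate the PPAR and RXR element (24 centres against 15 windows, Fisher's exact test, adjusted p = 0.228), ERR (Fisher's exact test, adjusted p = 0.672), MEF2 (Fisher's exact test, adjusted p = 0.672) or FOX (Fisher's exact test, adjusted p = 0.679) from the background. Against dinucleotide-shuffled centres all of these were more frequent at peaks, the PPAR and RXR element 6-fold, ERR 1.72-fold, MEF2 2.10-fold and FOX 1.35-fold (Fisher's exact test, adjusted p = 0.000205, 7.92e-08, 4.35e-50 and 1.43e-12). Against windows beside the peaks ERR, MEF2 and FOX were less frequent, at 0.754-fold, 0.573-fold and 0.812-fold (Fisher's exact test, adjusted p = 0.000113, 3.83e-68 and 2.20e-10). Against the matched background FOX was less frequent at promoter peaks alone (170 against 274, 0.620-fold, Fisher's exact test, adjusted p = 2.21e-06) and among the 5918 highest-scoring peaks (71 against 109, 0.651-fold, adjusted p = 0.0116), and MEF2 more frequent at distal peaks alone (1.13-fold, adjusted p = 0.0121). Promoter and distal peaks carried different motifs, in a comparison of intervals chosen after the data were seen. At promoter peaks NRF1 exceeded its background by 3.16 points (Newcombe 95% interval 2.75 to 3.58), KLF/SP by 3.11 points (2.48 to 3.75) and ETS by 1.90 points (1.58 to 2.24), while at distal peaks these differences were 0.0304, 0.00652 and 0.0717 points (Fisher's exact test, adjusted p = 0.384, 0.991 and 0.0529). AP1 was in excess by 4.44 points at distal peaks (4.15 to 4.73) and by 0.750 points at promoters (0.414 to 1.09), and TEAD by 1.61 points (1.35 to 1.86) and 0.382 points (0.0677 to 0.699). The intervals of promoter and distal peaks lay apart for 15 motifs, 9 of them higher at promoters and 6 higher at distal peaks.

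**Figure D4:**
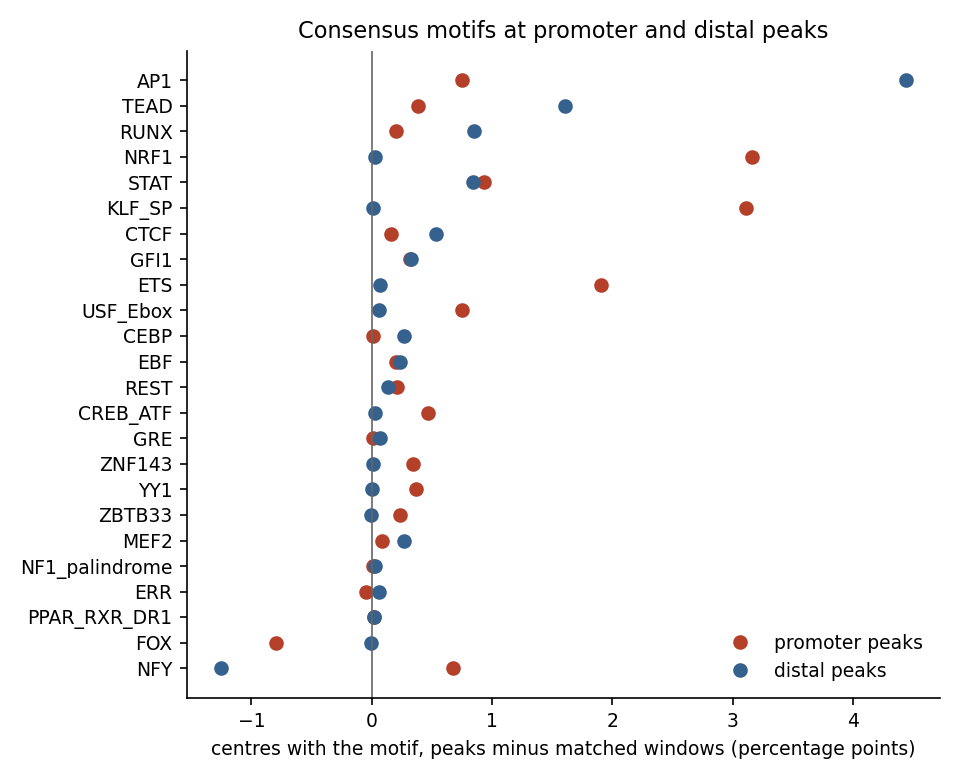
Difference between LSD1 peak centres and matched background windows in the percent of windows with an exact motif match (x axis, percentage points) for each of 24 motifs (y axis), for promoter and distal peaks, without error bars. AP1 reached 4.44 points at distal peaks, and NRF1 3.16 points at promoter peaks.

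Peak centres were richer in GC and CpG than random sites on the same chromosomes. The median GC content was 50% (quartiles 44.0 and 56.5%) against 42.0% (36.5 and 47.5%), and the median observed over expected CpG ratio was 0.250 against 0.150. Promoter peaks reached medians of 62.5% GC and 0.730 for CpG, and distal peaks 48.0% and 0.190. Over all peaks the differences of 8 points and 0.1 passed two-sided permutation tests (p = 1e-05 for each, the smallest the permutations can give), and the classes were not tested apart.

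Chromosome X carried far fewer LSD1 peaks than any autosome. It had 273 peaks, 1.67 per Mb, against a median of 25.2 per Mb for the autosomes, which ranged from 18.0 on chromosome 14 to 37.0 on chromosome 11. This was 15.1-fold lower, a ratio of 0.0663 with an exact Poisson 95% interval of 0.0587 to 0.0747 that covers counting error only. Of 948 protein-coding genes on chromosome X, 133 had a promoter peak (14%, 12 to 16.4%), while on the autosomes the share ran from 45.3% on chromosome 14 to 70.7% on chromosome 12. Chromosome Y held 14 peaks, 0.159 per Mb, and none of its 183 protein-coding genes had a promoter peak, which allows a share of up to 2.06%. No test was made of peak density between chromosomes, and the share of bound X genes is set against autosomal genes under the other observations below. The sex of the donor animals, the filters applied to reads on chromosome X and the control used in peak calling are not in the labels, so the density and the 14% describe the peak list and not the extent of LSD1 binding on this chromosome.

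**Figure D5:**
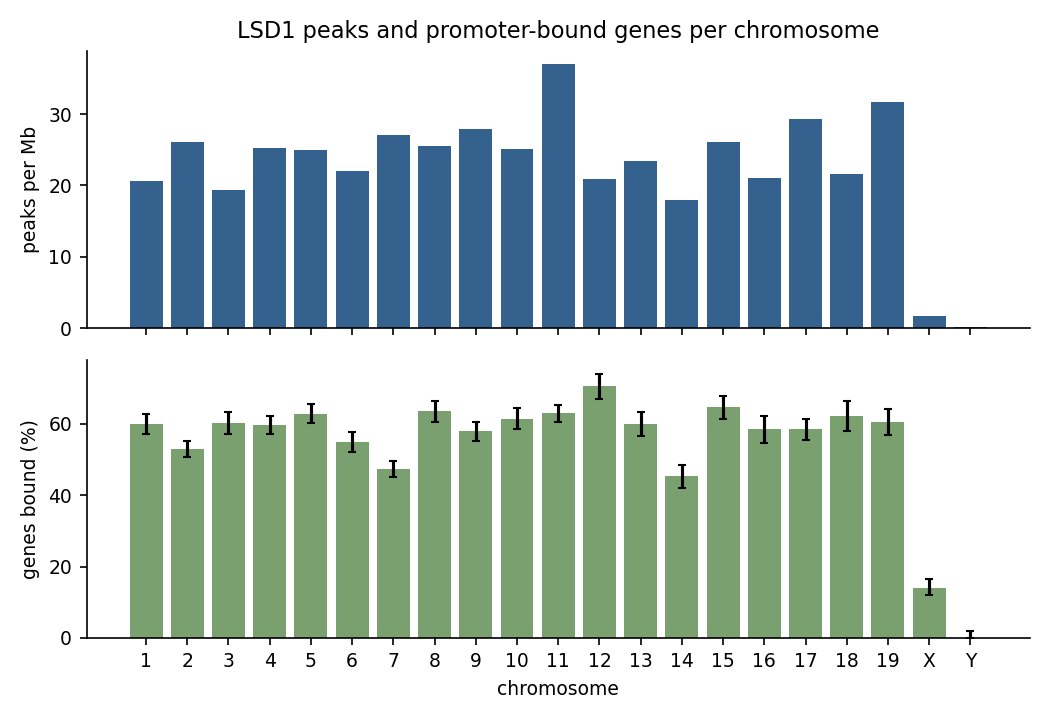
LSD1 peaks per Mb of assembled sequence (upper y axis) and percent of protein-coding genes with a promoter peak (lower y axis, with Wilson 95% intervals) for each chromosome (x axis). Chromosome X stood at 1.67 peaks per Mb and 14% of genes, and the lowest autosome at 18.0 peaks per Mb and 45.3%.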

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

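The alternatives below were fixed before the data were examined, except that autosomes alone and narrow width classes were tested only after the results had been seen. No paired analysis was possible because the series has 1 peak list from 1 library. Of 542 alternative values, 83 of the main results kept direction and side of the threshold, 16 moved, 7 changed direction and 2 lost the call. Among single lists and motifs 302 stayed the same, 47 moved, 9 changed direction, 38 lost a call and 38 gained 1. The promoter excess, the higher promoter scores and the GC and CpG differences kept their direction and call in all alternatives run for them, and the density on chromosome X, which has no test, stayed low in the 1 alternative run. The unknown depth limits what can be said of weak peaks, and the cause was not tested for any change below. Restricting the list to the 29591 highest-scoring peaks gave a median score of 193, and restricting it to 5918 peaks a median score of 597 and a median width of 1412 bp. With the 29591 peaks, untranslated regions went to 0.902-fold, and with the 5918 peaks to 0.439-fold, other exons to 0.828-fold and coding exons, no longer past the threshold, to 1.21-fold. Counting any overlap gave 0.974-fold for coding exons and 0.970-fold for untranslated regions, and promoters of 2.5 kb gave 1.02-fold for the latter, without a call. Introns turned to 1.00-fold (1.0036) with promoters of 500 bp and to 1.01-fold with 1 start per gene. For promoter lists, the count above chance, 2 in the main setting, was 11 with 3 below against unmatched genes, and 1 with midpoints inside the promoter or promoters of 500 bp. The preadipocyte list went to -11.2 points with the 5918 peaks, and the macrophage list to -39.2 points against unmatched genes. For nearby peaks, the count above chance, 2 in the main setting, was 10 with 1 below against unmatched genes, 0 with a 50 kb window, 4 with promoters left out and 1 with autosomes alone. For motifs, the number less frequent was 3 against windows beside the peaks, where NFY went to 1.10 points, ERR to -0.148 and MEF2 to -1.47. NFY was at 0.899 points with the 5918 peaks and 0.673 points at promoter peaks, FOX at 0.573 points against shuffled sequence and ZBTB33 at -0.00217 points at distal peaks, where 11 motifs were more frequent.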

Other observations

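The tests of gene families, of promoter scores per list, of 1 copy of chromosome X, of ribosomal protein genes and of the least repeated histone peaks were chosen only after the result was seen.

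Among 14 gene families picked by symbol on the autosomes, receptors of the nose were the least occupied relative to promoters of like CpG content. Olfactory receptors had 20 of 1127 promoters with a peak against 104 expected, vomeronasal receptors 1 of 327 against 19.9 and keratins, the filaments of epithelia and hair, 5 of 53 against 16.5 (permutation p = 0.0002, the smallest the permutations can give, and adjusted p = 0.0007 for each). Collagens, the fibrous matrix proteins, lay above chance with 29 of 43 against 21.7 (adjusted permutation p = 0.0213), as did zinc finger genes named Zfp with 276 of 385 against 255.9 (adjusted permutation p = 0.0219). Hox cluster genes, the patterning regulators, were occupied at 28 of 39 against 30.4 (adjusted permutation p = 0.635), but their median promoter score of 152 lay below the 320.3 of matched lists (adjusted permutation p = 0.0065). Klf genes, zinc finger regulators of differentiation, had a median score of 790 against 384 (adjusted permutation p = 0.013), proteasome subunits 202 against 332 (adjusted permutation p = 0.0317) and olfactory receptors 86.0 against 109 (adjusted permutation p = 0.0156). The counts and scores of Fox, Sox and Wnt genes, aminoacyl tRNA synthetases and mitochondrial ribosomal proteins did not pass. Random lists drew genes 1 by 1, while members of families such as the Hox clusters lie side by side and can share peaks. The family p-values treat such neighbours as independent and may be too small.

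Promoter scores gave another view of the fixed lists. The 20 occupied glycolysis and glucose uptake genes had a median promoter score of 642 against 314 for matched bound genes, and the 13 glucocorticoid genes 790 against 341 (adjusted permutation p = 0.0153 for each). Klf9 stands both in the glucocorticoid list and among the Klf genes. These were the 2 lists of the 17 tested that passed. The score of a gene is the highest over all its starts. Matching here and for the families held CpG content alone, not the number of starts or peak width. The cells had been treated with dexamethasone, a synthetic glucocorticoid, in the adipogenic mixture, and no untreated library was analysed here to compare with.

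Chromosome X had few peaks (273) and 14% of its promoters occupied, although peaks were found in all 18 of its 10 Mb segments. A lower CpG content of X promoters was argued against, since autosomal sets of the same CpG deciles averaged 46.0% and the lowest of 10000 sets was at 41.4%. Sequence marked as repeats in the reference at the promoter was argued against as well. Among promoters with less of it than the autosomal median, 18.5% (15.04 to 22.5%) of 411 X promoters were occupied, against 69.6% (68.7 to 70.4%) of 10338 autosomal ones. This measure took 1 start per gene and does not cover sequence duplicated between genes. Whether reads can be placed at X promoters was not measured. A single copy of chromosome X per cell may account for part of the deficit and cannot be told apart from other sources. The sex of the donors is not in the labels. A Poisson model removed 1 of every 2 reads behind each autosomal promoter score and left 14.9 to 33.8% bound. This range depended on an assumed score scale, a background of 1 to 30 reads and the minimum score. The lowest share came from the background of 30 reads and a minimum score of 76.0. The background itself was not reduced with the reads, so the model may overstate the loss and does not decide the question. Removal of X reads by a filter, or a control with another number of X copies, was not tested, and neither was a biological explanation, as the design has no group for it.

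The 67 replication-dependent histone genes on the autosomes all had a promoter peak, against 59.1 expected (permutation p = 0.0002, the smallest the permutations can give), but they share 43 peaks, whose median score was 1899.7, and the median of 3100 over genes is the tied top score and counts shared peaks more than once. Merging of neighbouring promoters into 1 peak was argued against for the 19 histone peaks that cover a single gene. Their median score percentile was 98.2 among such peaks, above all random sets (14.6 to 84.5). Width, whose log10 went with log10 score across peaks (Pearson r = 0.867), was not matched, and the 19 include a peak of 6433 bp. The comparison therefore speaks to merging and not to width or repeated sequence. Whether reads shared between histone copies play a part stays open. The 16 peaks with less than 10% of repeated 32-base words, a limit set in advance, had a median percentile of 98.9 (random sets 15.6 to 86.7). This came from 9 peaks above 4%. The 7 below it had a median of 76.9 (32.3 to 98.4), inside the range of random sets (4.46 to 96.6, one-sided p by random sets = 0.0538). The 7 were also narrower, with a median width of 1414 bp against 3117 bp, so repeats and width cannot be told apart. Over all 43 histone peaks, repeated words and percentile were not clearly related (Spearman rho = 0.241, p = 0.119). High scores at all heavily transcribed genes were argued against by the ribosomal protein genes, at percentile 45.9 of matched lists, but glycolysis and glucose uptake genes lay at percentile 99.94 and transcription was not measured, so a part of heavy transcription stays open. A preference of LSD1 for histone genes and an over-recovery of their chromatin in any immunoprecipitate may both account for the pattern and stay open, and no biological explanation was tested because the design has no group for it.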
